A study of Mus musculus with 10 samples.

How the data were processed

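The samples were total RNA from livers of FVB mice, 4 untreated and 6 with LKB1 overexpressed from an injected plasmid, biotin-labelled after amplification and hybridised to Illumina bead arrays, per the labels' protocols. The series' design text counts mice, so each array was taken as 1 animal. Group and replicate number came from the labels. One title of the LKB1 group can be read as the gene's name or as replicate 1, and was read as replicate 1. The numbers 1, 2 and 4 occur in both groups and were not used to pair mice. The time of day at which livers were taken, the feeding state and an injection given to control mice are not given in the sources used here.

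The deposited table of the whole series gives for each probe and array an average signal, a linear intensity that is not normalized between arrays, and a detection p-value, per the file headers. Whether the scanner software had already subtracted background from the deposited intensity is not stated. At a detection p-value near 0.5 the deposited intensity lay between 18.16 and 19.52 on all arrays, so a background level remained. The authors' processed values are on a scale read as log2 from their comparison with each array's intensities, as the deposited table does not name the base. Their median was 4.36 in every column and their ranks within each column matched those of that column's own array, so the arrays had been brought to equal distributions. The package lumi is named in the submitters' processing notes, with no version. No per-sample column was left unmapped (0 columns).

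Intensities were background-corrected by normexp with parameters taken from the detection p-values, an offset of 16 was added, and arrays were quantile-normalized and put on the log2 scale, with neqc of limma 3.58.1 in R 4.3.3. Probes detected at a detection p under 0.05 on at least 4 arrays were kept, 16803 of 45281. Gene symbols came from GEO's platform annotation: 34885 probes had 1 symbol, 18 had several and 10378 were not listed there and stay unnamed here. Of the annotated probes, 34807 were matched by Entrez gene number to the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. That table was used for names only. No coordinates are given, as the files name no genome build. A gene was represented by its kept probe with the highest mean over all 10 arrays, and 3385 of 9725 genes had more than 1 kept probe. Values of other probes stand beside a named gene where they differ from it markedly.

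The groups were compared with lmFit and eBayes of limma, with no covariate, and Benjamini-Hochberg adjustment over all kept probes at 0.05. All tests were two-sided. Gene lists for pathways, complexes and cell types, 47 in all, were written before the data were examined. One of them, of sex-linked genes, served as a check, 3 had under 5 measured genes, and 43 were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists. Beside it stand camera with the correlation estimated from the data, fry, which asks whether a list's genes move on balance one way or, in its mixed form, whether they change in either direction, and an exact permutation of the list mean over all 210 splits of the 10 arrays, whose smallest possible p is 0.00476, so that a single list cannot pass the adjustment over the lists by this test. Adjusted over the list alone means Benjamini-Hochberg over the measured members of 1 list. Confidence intervals are at 95%.

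Named genes followed a rule set before the data were examined: Stk11; with fewer than 5 genes called, the 10 genes of smallest p that have more than a clone or predicted name; and members of the fixed lists, 2 of smallest p where none was called over all genes. Clock genes other than Nr1d2 and Tef, and Sesn2, Rgs16 and Upp2, were added after their values were seen.

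The files name no chip or date. The arrays were clustered on the 24495 probes detected on no array, and the tree was cut into 2 sets, a number fixed by the cut. The mean Spearman correlation was 0.522 within and 0.482 between sets. Since the clustering used these same correlations, a higher value within sets follows from it. Between the sets, 133 kept probes had an adjusted p under 0.05. Each set held mice of both groups, so values with the set as a block and within each set are given.

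All 4 Xist probes were below detection on every array (0 detected readings), and 2 of 8 probes of Y-linked genes were kept, near background.

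The fit and the list test were tested on simulated data: 5 simulations on the 9725 genes with the real means and residual spreads, independent normal noise and 200 genes changed. At a fold change of 1.5, 64.5% of the changed genes were recovered, at 2-fold 95.8% and at 3-fold 98.5%, with a mean of 4.8 false calls per simulation. The list of respiratory chain genes, moved by 0.2 on the log2 scale, was called in 5 of 5 simulations, with 0 other lists. That shift was larger than the median of most lists called in the real data, so recovery of smaller shifts was not tested. Simulated genes were independent, which genes of real livers are not, so these simulations do not give the rate of false list calls in real livers.

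Alternatives covered the background step (normexp with an offset of 50, none), the scaling (equal array medians, cyclic loess, the authors' values), the probe filter (none, detected on all 10 arrays), the model (trend and robust eBayes, array weights, the replicate number as a block), each array left out in turn, the mean over a gene's probes, a fold change of at least 1.5, an adjusted p under 0.01, and the list tests. With the replicate number as a block, the comparison rests on the mice numbered 1, 2 and 4, as no other number occurs in both groups. The array set as a fixed or random block, fits within each set, the count at unadjusted p, the exact permutation of list means and fry in either direction were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.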

Results

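Liver RNA of 10 FVB mice, an inbred laboratory strain, was hybridised to Illumina bead arrays, with 1 array per mouse. In 6 mice LKB1 had been overexpressed by a wild-type plasmid given into the tail vein, at 1 injection per week over 8 weeks, and 4 mice were untreated. LKB1, the product of Stk11, is a serine/threonine kinase and tumour suppressor that activates AMPK and the AMPK-related kinases. The series title places the work in a study of SUMOylation and the movement of LKB1 between nucleus and cytoplasm in liver cancer, and the comparison asks which liver transcripts differed between mice with added LKB1 and normal mice. The labels name hepatocytes as the source and liver as the tissue, and whether hepatocytes were isolated is not given in the sources used here. Of the 45281 probes on the array, between 15374 and 16839 were detected per array, and 16803 probes representing 9725 genes were kept. Pairs of arrays correlated at r = 0.983 to r = 0.994 over the kept probes, and the number of arrays limits the precision of every value below. Probes at background split the 10 arrays into set A (untreated 1 and 2, LKB1 1, 2 and 4) and set B (untreated 3 and 4, LKB1 5, 6 and 7). The control mice are labelled as untreated, so the plasmid, the injections and the added LKB1 came together in the 6 treated mice.

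Stk11 mRNA differed between the groups by less than the spread between mice. Its probe was detected on all 10 arrays, with a log2 intensity of 9.60 ± 0.12 (SD, n = 4) in untreated livers and 9.66 ± 0.08 (SD, n = 6) in LKB1 livers. The fold change was 1.04, with a 95% confidence interval from 0.922 to 1.18 and a limma adjusted p of 0.93; with array medians made equal the log2 fold change was -0.15, on a scale where the median of all genes lay at -0.157. Stk11 differed by 0.10 in array set A and 0.02 in array set B. Which part of the transcript this probe covers, and whether it can bind a transcript made from the plasmid, is not given in the sources used here, so whether the value includes LKB1 mRNA from the plasmid cannot be read from it. The genes of the LKB1 complex, the AMPK subunits and the AMPK-related kinases were split evenly, with 8 of 16 measured members higher and 8 lower, a median log2 fold change of -0.01 and an adjusted p of 0.899 (camera). The members of smallest p were Mark3, a microtubule affinity-regulating kinase, at a log2 fold change of 0.19 ± 0.10 (SE), or -0.01 with array medians made equal, and the salt-inducible kinase Sik1 at 0.28 ± 0.17 (SE). Neither passed the test, the other probe of Mark3 gave 0.10, and leaving out 1 mouse took Mark3 to 0.11 (untreated replicate 3) and Sik1 to 0.13 (untreated replicate 1).

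No gene passed an adjusted p of 0.05 between LKB1 and untreated livers (limma, 0 of 9725 genes and 0 of 16803 probes), and the smallest adjusted p was 0.166. The genes of smallest p separated the groups on every array at their brightest probe, which their choice by p favours. Cxcl1, a chemokine that attracts neutrophils, was 3.62-fold lower in LKB1 livers (log2 fold change -1.86 ± 0.28, SE). Gadd45a, a growth arrest and DNA damage gene, was 2.21-fold lower on its brighter probe and 2.18-fold lower on its other probe. Lower values were also measured for Rnf186, a ubiquitin ligase (-0.92 ± 0.18, SE), for Trib3, a stress-induced pseudokinase (-0.89 ± 0.17, SE), and for Birc5, which encodes survivin and lay near background (-0.41 ± 0.08, SE). Higher values were measured for Dusp1, a MAP kinase phosphatase (0.92 ± 0.15, SE), for Slc25a25, a mitochondrial carrier (0.79 ± 0.14, SE), for Mir17hg, the host transcript of a microRNA cluster (0.69 ± 0.12, SE), and for Pkdcc, a secreted kinase (0.52 ± 0.08, SE). Asap2, an ARF GTPase-activating protein, was higher by 0.86 ± 0.15 (SE) on its brightest probe but by 0.37 and 0.12 on its other probes. The adjusted p was 0.166 for Cxcl1, Gadd45a, Dusp1, Slc25a25, Mir17hg, Pkdcc and Asap2, and 0.257 for Trib3, Rnf186 and Birc5, and in each of these 10 genes all 6 LKB1 arrays lay on the same side of all 4 untreated arrays. Such a separation occurred in 128 genes, 1.32% of those tested, against 0.952% by chance. On the other probe of Pkdcc, at 0.42, the groups overlapped.

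**Figure D1:**
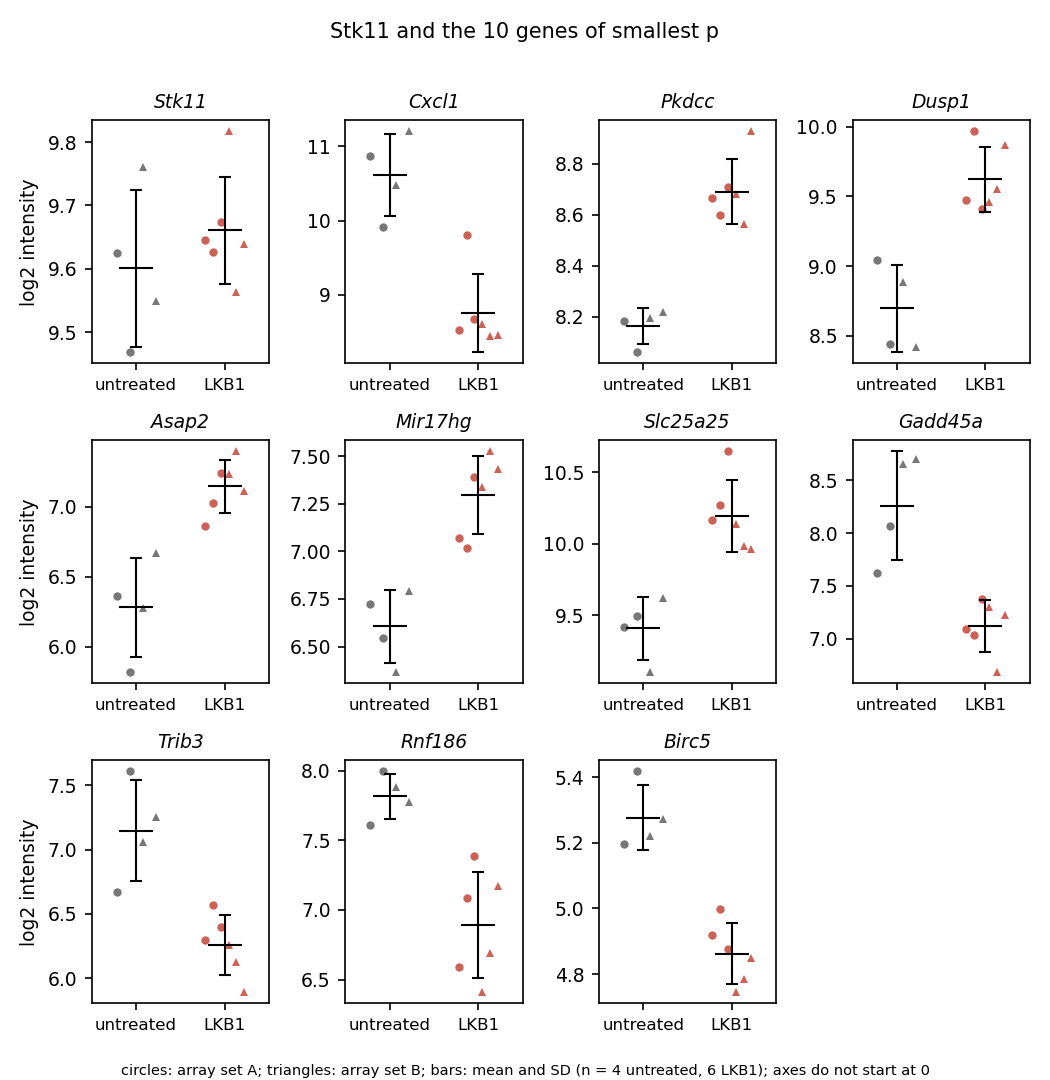
Log2 intensity per mouse of Stk11 and of the 10 genes of smallest p, with untreated livers (n = 4) on the left and LKB1 livers (n = 6) on the right of each panel; points are mice, circles and triangles mark array sets A and B, and bars give mean and SD. Stk11 overlaps between the groups, whereas for Cxcl1 the LKB1 livers lie between 8.45 and 9.81 and the untreated livers between 9.92 and 11.20.

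At an unadjusted p under 0.05 there were 613 genes, 312 higher and 301 lower in LKB1 livers, against 486 at 5% of independent genes and a median of 380 in other splits of the mice. With the array set as a block, other splits had a median of 439. Since 0 genes were called, the share of higher calls is undefined. Without LKB1 replicate 2, the treated mouse with the highest Cxcl1, Cxcl1 passed the test (adjusted p = 0.00788, limma), against a range from 5.9e-05 to 0.803 over the settings tried. Without untreated replicate 2 the count at an unadjusted p under 0.05 was 374. With array medians made equal, 11 genes passed on that shifted scale, all of them lower in LKB1 livers and among them Cxcl1, Gadd45a, Trib3, Rnf186, Cyp3a11, the clock genes Tef, Dbp and Ciart, and Rgs16. The 10 genes of smallest p had the same direction within each set, and Cxcl1 differed by -1.39 in set A and by -2.33 in set B. With the array set as a block, 798 genes had an unadjusted p under 0.05 and 0 genes were called (smallest adjusted p = 0.161, limma).

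Genes of the circadian clock, the daily oscillator of liver transcription, had the list median farthest from 0. Of 17 measured members, 8 fell and 3 rose when p was adjusted over the list alone, and none passed over all genes except Tef, Dbp and Ciart with array medians made equal (adjusted p = 0.0211, 0.0211 and 0.0259, limma). Dbp, a clock-driven transcription factor of the PAR bZIP family, was 4.26-fold lower in LKB1 livers, with a log2 intensity of 9.98 ± 1.23 (SD, n = 6) against 12.07 ± 0.49 (SD, n = 4). Its relative Tef fell by 0.95 ± 0.19 (SE), and the nuclear receptors Nr1d2 and Nr1d1, which repress Arntl, fell by 0.61 ± 0.12 and 0.70 ± 0.20 (SE). The other members that fell were Usp2 (-1.35), Ciart (-1.33), Per3 (-0.78) and Cry2 (-0.53). Usp2 and Per3 were highest in untreated replicate 2, without which they differed by -0.86 and -0.47. The activators of the clock went the other way, with log2 fold changes of 0.57 ± 0.20 (SE) for Npas2, 0.48 ± 0.20 (SE) for Arntl and 0.33 ± 0.12 (SE) for Clock, whose other probe gave 0.58. Npas2 was detected in 1 of 4 untreated and 4 of 6 LKB1 livers, Ciart in 4 of 6 and Per3 in 3 of 6 LKB1 livers, so their values lay near background. Arntl and the other Clock probe lay near background too, at 4.94 and 4.74 in untreated livers, and were detected in 3 and 2 of these. Nr1d2 and Tef were named by a rule fixed before the data were examined, and the other clock genes were chosen after their values were seen.

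The clock list as a whole was lower, with a median log2 fold change of -0.41, a list mean below that of every untreated mouse in 6 of 6 LKB1 mice, and an adjusted p of 0.000568 (camera, preset correlation). With an estimated correlation between genes the adjusted p was 0.786, and the exact permutation test of the list mean gave p = 0.0143, or 0.546 after adjustment over the 43 lists, which a single list cannot pass by this test. With fry, the list had an adjusted p of 0.732 for a shift on balance one way and of 0.0251 for change in either direction. Within the array sets its unadjusted camera p was 0.000668 in set A and 3.21e-05 in set B, lower in each.

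**Figure D2:**
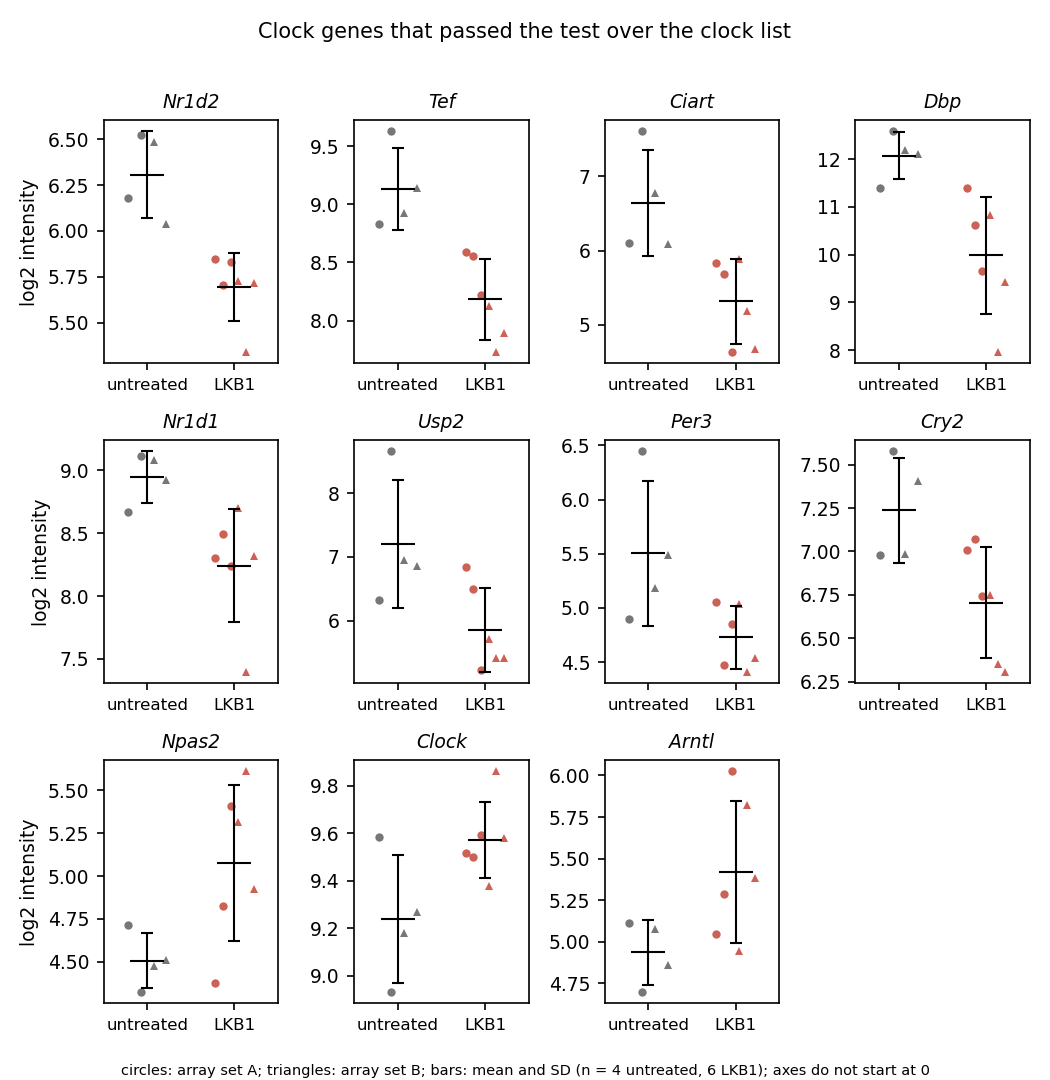
Log2 intensity per mouse of the 11 clock genes that passed the test over the clock list, with untreated livers (n = 4) on the left and LKB1 livers (n = 6) on the right; points are mice, circles and triangles mark array sets A and B, and bars give mean and SD. Dbp lies between 11.40 and 12.58 in untreated livers and between 7.96 and 11.39 in LKB1 livers, and Npas2, Clock and Arntl have the higher mean in LKB1 livers.

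Markers of Kupffer cells and macrophages were higher in LKB1 livers, in 20 of 21 measured genes, with a median log2 fold change of 0.21 and a list mean above the average of the untreated mice in 6 of 6 LKB1 mice (adjusted p = 0.000568, camera). With an estimated correlation the adjusted p was 0.786. Single mice overlapped, and untreated replicate 3 lay above LKB1 replicates 2, 4, 6 and 7. No member passed singly, and the complement components C1qa and C1qb, made by macrophages, had log2 fold changes of 0.37 ± 0.14 and 0.43 ± 0.17 (SE), or of 0.20 and 0.28 without untreated replicate 4. Interferon-stimulated genes were higher in 27 of 32 members, with a median of 0.18 and an adjusted p of 0.000568, or 0.786 with an estimated correlation. Stat2, a transducer of interferon signals, was at 0.29 ± 0.10 (SE), whereas the interferon regulatory factor Irf1 was at -0.34 ± 0.14 (SE) on its brightest probe and at -0.29, -0.18 and -0.11 on its others. Genes of antigen presentation by MHC molecules were higher in 16 of 17 members, with a median of 0.14, or -0.02 with array medians made equal, which is still above the shift of all genes. The adjusted p was 0.000601, or 0.786 with an estimated correlation. The class II gene H2-Ab1 was at 0.53 ± 0.27 (SE), with 0.48 and 0.27 on its other probes, and its chaperone Cd74 at 0.42 ± 0.23 (SE), or 0.27 without untreated replicate 4. Interferon and MHC list means lay above the average of the untreated mice in 5 of 6 LKB1 mice. The exception, LKB1 replicate 2, had the lowest mean of all mice in both lists, at -0.28 and -0.34. Single mice overlapped: LKB1 replicates 4 and 6 lay below untreated replicate 3 for interferon and below untreated replicate 1 for MHC genes.

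Within array set A the interferon and MHC lists had unadjusted camera p-values of 0.0566 and 0.466, and within set B of 3.31e-06 and 1.08e-08, while the Kupffer list had 0.00108 and 0.000181. H2-Ab1 differed by 0.14 in set A and 0.91 in set B. Without untreated replicate 4 the Kupffer list had a median of 0.06 and an adjusted p of 0.239, against medians of 0.33 without untreated replicate 3 and 0.14 without LKB1 replicate 5, and the interferon and MHC lists each had an adjusted p of 0.0456.

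Cytosolic heat shock genes were higher in 11 of 14 members, with a median log2 fold change of 0.16. With array medians made equal the median was -0.02, still above that of all genes at -0.157 on that scale. The list mean lay above the mean of the untreated mice in 6 of 6 LKB1 mice, but that of untreated replicate 1 was higher than all LKB1 mice except replicate 7. The adjusted p was 0.0133 (camera), or 0.786 with an estimated correlation. Hspa4l, a chaperone of the HSP110 family, rose by 0.70 ± 0.16 (SE) when p was adjusted over the list alone, and Hsp90aa1 was at 0.38 ± 0.13 (SE), with 0.24 on its other probe. Both genes lay near background, at 4.93 and 5.07 in untreated livers, and Hspa4l was detected in 3 of 4 of these. By exact permutation over all mice, the heat shock list mean had p = 0.114. The heat shock list had an unadjusted camera p of 0.724 within array set A and of 1.55e-05 within set B. Its call was lost without untreated replicate 3 (adjusted p = 0.155), untreated replicate 4 (0.403, with a median of 0.09), LKB1 replicate 1 (0.0561) or LKB1 replicate 7 (0.0534), among probes detected on all 10 arrays (0.112) and with array weights (0.0637).

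Genes of the SUMO pathway, which attaches and removes the small modifier SUMO, were higher in 12 of 14 members. The median was small, at 0.10. With array medians made equal it was -0.09, still above the median of all genes at -0.157 on that scale. The list mean lay above the average of the untreated mice in 6 of 6 LKB1 mice, but LKB1 replicates 1 and 4 lay below untreated replicates 3 and 4. The adjusted p was 0.0435 (camera), or 0.786 with an estimated correlation. By exact permutation over all mice, the SUMO list mean had p = 0.0524. Within the array sets the unadjusted camera p was 0.0243 in set A and 0.0354 in set B, higher in each. Adjusted over the lists it was 0.123 and 0.122, so the call was lost within each set. The SUMO proteases Senp5 and Senp1 had the smallest p, at 0.29 ± 0.10 and 0.21 ± 0.10 (SE) on their brighter probes, but their other probes gave 0.06 and -0.15, and Senp1 was at 0.13 without untreated replicate 1. The SUMO call was lost without untreated replicate 1 (adjusted p = 0.171), 2 (0.0967) or 4 (0.0584), and without LKB1 replicate 2 (0.0678), 5 (0.0931), 6 (0.0634) or 7 (0.0511). It was also lost with the replicate number as a block (0.21), with array medians made equal (0.28), with no filter on dim probes (0.05004) and among probes detected on all 10 arrays (0.0516).

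Subunits of the respiratory chain and ATP synthase were lower in 44 of 49 measured genes. The shift was small, with a median log2 fold change of -0.06, a list mean below the average of the untreated mice in 6 of 6 LKB1 mice, LKB1 replicate 4 only barely, and an adjusted p of 0.000601 (camera). With an estimated correlation the adjusted p was 0.786. Single mice overlapped, and untreated replicate 4, without which the median was -0.10, lay below LKB1 replicates 2, 4 and 6. No subunit passed singly, and Ndufb7 of complex I and Cox6c of complex IV had log2 fold changes of -0.20 ± 0.08 and -0.21 ± 0.11 (SE), or -0.33 for Cox6c without untreated replicate 4. The respiratory list was lower within array set A (unadjusted p = 0.000534) and within set B (unadjusted p = 0.0178). With the replicate number as a block its median was -0.03 and its adjusted p 0.100.

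Drug metabolism genes were lower in 22 of 34 members, with a median of -0.05, a list mean below the average of the untreated mice in 5 of 6 LKB1 mice and an adjusted p of 0.0125 (camera), or 0.786 with an estimated correlation. Single mice overlapped, and untreated replicate 1 lay below LKB1 replicates 1 and 2. Cyp3a11, a major drug-oxidising cytochrome P450 of mouse liver, fell by 0.66 ± 0.13 (SE) when p was adjusted over the list alone, and Nr1i2, the nuclear receptor PXR that drives Cyp3a11 transcription, was at -0.39 ± 0.13 (SE). By exact permutation over all mice, the drug metabolism list mean had p = 0.0571. Within array set A the drug metabolism list had an unadjusted camera p of 0.166, and within set B of 0.000387. Its call was lost without untreated replicate 2 (adjusted p = 0.179) or LKB1 replicate 5 (0.0543), among probes detected on all 10 arrays (0.0516), and with the replicate number as a block (0.468). Its median without untreated replicate 1 was -0.03.

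**Figure D3:**
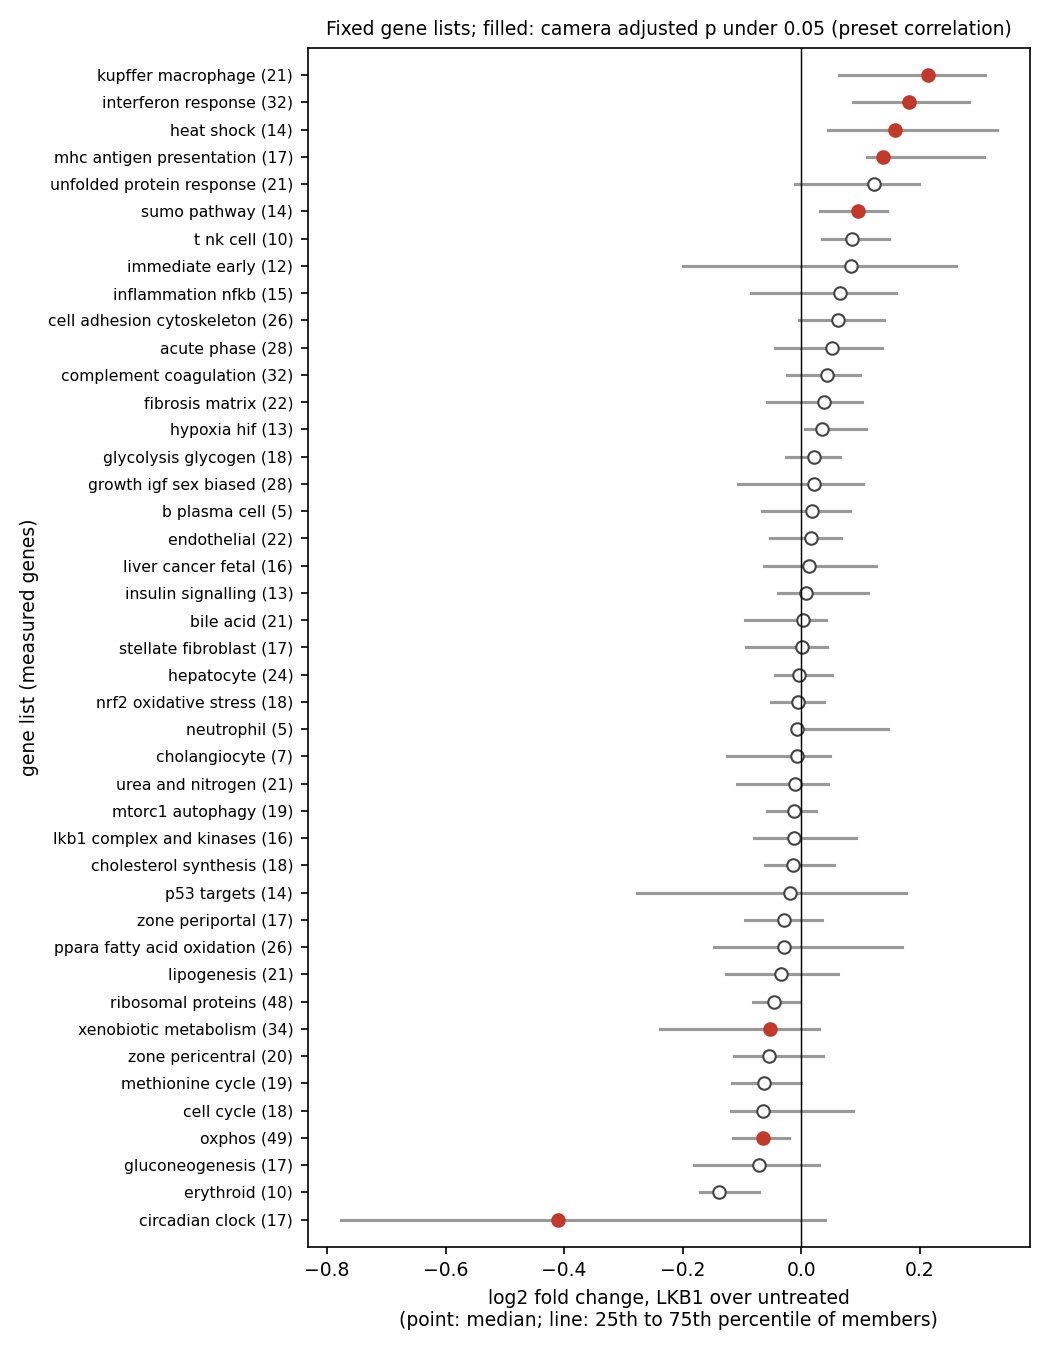
Median log2 fold change of each of the 43 gene lists tested, LKB1 over untreated livers, on the horizontal axis, with the number of measured genes in brackets; points are list medians, lines run from the 25th to the 75th percentile of the members, and filled points passed an adjusted p of 0.05 with camera at the preset correlation. The clock list lies lowest, at -0.41, and the Kupffer and macrophage list highest, at 0.21.

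Glucose metabolism genes did not pass the test as a group. Gys2, the liver glycogen synthase, fell by 0.56 ± 0.14 (SE) when p was adjusted over the list of glycolysis and glycogen genes alone, and its other probe gave -0.64. Ppp1r3b, a subunit that directs a phosphatase to glycogen, was at 0.61 ± 0.23 (SE). The list had a median of 0.02 and an adjusted p of 0.778 (camera). Gluconeogenesis genes had a median of -0.07, from -0.135 to -0.005 with 1 array left out, and an adjusted p of 0.779. Among them G6pc, the catalytic subunit of glucose-6-phosphatase, was at 0.57 ± 0.17 (SE) and Pck1, cytosolic PEP carboxykinase, at -0.51 ± 0.19 (SE). Pck1 differed by 0.00 in array set A and by -1.03 in set B. Ppara, the nuclear receptor that controls fatty acid oxidation, fell by 0.46 ± 0.10 (SE) when p was adjusted over its list alone, and the list of fatty acid oxidation genes had a median of -0.03 and an adjusted p of 0.62. That list was lower in array set A (unadjusted p = 0.000951) and higher in set B (unadjusted p = 0.0515). It was called as lower without LKB1 replicate 7 (adjusted p = 0.0379), with the replicate number as a block (5.88e-06) and within set A (0.00877). With an estimated correlation its adjusted p over all arrays was 0.942. Aldh3a2, a fatty aldehyde dehydrogenase, was at -0.29 ± 0.12 (SE). Fatty acid and triglyceride synthesis had a median of -0.03 and an adjusted p of 0.62, with Aacs at 0.50 ± 0.17 (SE) and Lpin2 at -0.79 ± 0.31 (SE), or -1.19 without untreated replicate 3. The synthesis list too was lower in set A (unadjusted p = 0.0042) and higher in set B (unadjusted p = 0.372). It was called as lower with the replicate number as a block (adjusted p = 0.0458) and within set A (0.0274). Its adjusted p over all arrays was 0.942 with an estimated correlation.

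Targets of p53 went both ways. Cdkn1a, the cell cycle inhibitor p21, rose 2.57-fold (log2 fold change 1.36 ± 0.30, SE) when p was adjusted over the list alone, and its other probe gave 0.72. Cdkn1a was detected in 3 of 4 untreated livers. Gadd45a fell in the same test, as did Sesn2, a sestrin, by 0.46 ± 0.12 (SE); Sesn2 was chosen after its values were seen. The p53 list had a median of -0.02 and an adjusted p of 0.692 (camera), and an adjusted p of 0.00152 for change in either direction (fry). Among immediate early genes Dusp1 rose and Junb, a subunit of AP-1, fell by 0.45 ± 0.14 (SE) over the list alone (list median 0.08, adjusted p = 0.49, camera). Birc5 fell in the cell cycle list (median -0.06, adjusted p = 0.596, camera), in which E2f1 was at -0.30 ± 0.11 (SE). The hypoxia target Ndrg1 rose by 0.80 ± 0.22 (SE) over its list alone, but by 0.50 at an unadjusted limma p of 0.0553 on its other probe. P4ha2 was at -0.15 ± 0.09 (SE), with -0.28 on its other probe, and the hypoxia list had a median of 0.03 (adjusted p = 0.609, camera). The list of ER stress genes had a median of 0.12 and an adjusted p of 0.0859 (camera), or 0.786 with an estimated correlation. Without untreated replicate 1 its median was 0.23 and its adjusted p 0.00128, and within array set B the adjusted p was 0.00469. Among ER stress genes Trib3 fell over the list alone. Atf4, which drives Trib3 transcription, was at 0.38 ± 0.15 (SE) on its brighter probe, or 0.22 without untreated replicate 4, and 0.13 on its other probe. Cxcl1 fell in the list of cytokines and NF-kB targets (median 0.06, adjusted p = 0.899, camera), a list whose mean and test were below 0, and the NF-kB inhibitor Nfkbia was at -0.29 ± 0.11 (SE). Acute phase genes had a median of 0.05 and an adjusted p of 0.596 (camera), with Socs3, a feedback inhibitor of cytokine signals, at -1.18 ± 0.42 (SE) and Saa3 at 0.40 ± 0.21 (SE). Socs3 differed by -0.37 in array set A and by -1.98 in set B, and by -0.78 without untreated replicate 3.

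Markers of other cell types did not pass the test over all arrays in the main setting. Within array set A, stellate cells and fibroblasts were called as lower (adjusted p = 0.00877, camera). Hepatocyte markers were split between 12 higher and 12 lower (median 0.00, adjusted p = 0.899, camera), and the pericentral and periportal zones had medians of -0.05 and -0.03 (adjusted p = 0.609 and 0.62). Endothelial cells had a median of 0.02 (adjusted p = 0.641), stellate cells and fibroblasts of 0.00 (0.779; unadjusted p = 0.000912, lower, in array set A and 0.129, higher, in set B), bile duct cells of -0.01 (0.752), T and NK cells of 0.09 (0.314), B and plasma cells of 0.02 (0.899), neutrophils of -0.01 (0.652) and red blood cells of -0.14 (0.651). With 1 mouse left out, the median of red blood cell markers ranged from -0.21 (untreated replicate 1) to -0.03 (LKB1 replicate 4), and that of T and NK cells was 0.02 without untreated replicate 4. With array medians made equal, T and NK cells were called as higher (adjusted p = 0.0336, camera). Their median there was -0.04, where that of all genes lay at -0.157. With an estimated correlation in the main setting their adjusted p was 0.848. Markers of platelets, pancreas, and fat and muscle had 4 measured genes each and were not tested.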

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

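Of the tests in this part, those on the clock activators, on the array sets, on splits that keep the array sets balanced and on red blood cell markers were chosen after the result was seen. Single mice far from the rest of their group were found in 6 of 136 groups of values examined, where chance gives about 1 in 20, or 6.8.

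Nr1d2 and Nr1d1 each had LKB1 replicate 6 far below the other 5 LKB1 livers: 5.34 against 5.71 to 5.85 for Nr1d2, a gap of 0.7208 of the group's range, and 7.39 against 8.24 to 8.70 for Nr1d1, a gap of 0.6477. That mouse also had the lowest Dbp, at 7.96.

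A candidate explanation for the clock pattern is that the groups were caught at different clock phases, which would lower genes in phase with Dbp outside the clock list too. Of 5 such genes named before the test, 4 were measured. Their mean differed by -0.817 in LKB1 livers (exact permutation p = 0.0143). It rests on Rgs16 (-2.09), the largest change of all genes, and Upp2 (-1.17), both named singly only after their values were seen. Nampt and Lonrf3 were level at 0.00 and -0.01, but lay near background, at 4.96 and 5.07 in untreated livers. The activators Arntl, Npas2 and Clock were higher by 0.461 on average (exact permutation p = 0.0286), but they are part of the pattern and decide nothing. At the preset correlation, the clock call held with any array left out, with a highest adjusted p of 0.00796 without LKB1 replicate 7 (camera). The larger of the 2 within-set p-values was 0.000668. These values argue against a dependence on 1 mouse or on the array sets at that correlation only. With an estimated correlation the list did not pass (adjusted p = 0.786). A clock p as small came from 5 of 100 splits of the mice, the real one included, and from 3 of the 100 balanced splits with the array set as a block. Lower Dbp-phase genes would also follow from a weaker clock at the same phase, so a phase difference is not established. Whether one would come from the time of collection or feeding, or from LKB1 or the injections acting on the clock, was not tested and stays open.

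C1qa had untreated replicate 4 far below the other untreated livers, at 6.31 against 6.96 to 7.04, a gap of 0.8976 of the range.

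For the macrophage, interferon and MHC pattern, untreated replicate 4 had the lowest list mean of each among untreated livers, and the call for the Kupffer list may rest on it, since without it the adjusted p was 0.239. At the preset correlation, the interferon and MHC lists passed with any 1 array left out, at adjusted p-values of up to 0.0456 and 0.0456 (camera). With estimated correlations of 0.305 and 0.530, neither passed over all arrays (adjusted p = 0.786 each). Whether they depend on 1 mouse is therefore not settled. More resident Kupffer cells in LKB1 livers stays open: the mean of their 6 measured markers, all of them members of the macrophage list and so part of the pattern, was higher by 0.161 with an exact permutation p of 0.243. More blood left in those livers stays open too, as Kupffer minus red blood cell markers differed by 0.279 with an exact permutation p of 0.186, and LKB1 itself as a cause was not tested apart from the injections. If hepatocytes were isolated, these lists could also report how pure each preparation was, which was not tested.

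Cxcl1 had LKB1 replicate 2 above the other LKB1 livers, at 9.81 against 8.45 to 8.68, a gap of 0.8344 of the range. Cyp3a11 had untreated replicate 1 below the other untreated livers, at 12.49 against 13.07 to 13.08, a gap of 0.9699. Ndufb7 had untreated replicate 4 at 7.42 against 7.56 in the other untreated livers, a gap of 0.9847 within a narrow range.

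With 0 genes and 0 probes called, splits of the mice into 4 and 6 can say nothing about chance, since 100 of 100 must give at least as many genes and 100 of 100 as many probes; the highest of the other splits was 1 in each. The 613 genes at an unadjusted p under 0.05 were equalled by 16 of 100 splits, with 1250 in the highest, so chance is not excluded. That highest split set untreated 3 and 4 with LKB1 5 and 7 against the rest, all of array set B, and points to a structure of the arrays. With the array set as a block, a test added after the unblocked splits were seen, the real split gave 798 such genes and 2 of the 100 splits that keep the balance of the sets gave as many, the real one included, the highest other giving 821. That share argues against chance for this count, but as count and test were both chosen after the result was seen, it does not settle the question. For the 8 gene lists called, chance is not excluded: 29 of 100 splits gave as many, with 15 in the highest, and with the array set as a block 22 of 100, with 16 in the highest. Without the block, the other splits had a median of 5 lists called.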

How the results depend on the processing

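The settings by array set, the exact permutation of list means, fry in either direction and the count at unadjusted p were chosen after seeing the data. The count of genes called stayed at 0 in all settings but 2. With array medians made equal, 11 genes and 15 probes were called, all lower in LKB1 livers, where that scaling moved the median of all genes to -0.157. Without LKB1 replicate 2, 1 gene and 1 probe were called, the gene being Cxcl1 (adjusted p = 0.00788, range over its settings from 5.9e-05 to 0.803); the range with 1 array left out was 0 to 1 for genes and for probes. The cause of both was not tested. Genes at an unadjusted p under 0.05 numbered 1230 with no filter on dim probes, where 19057 genes were tested, and 374 to 761 with 1 array left out, the lowest without untreated replicate 2. Gene lists called numbered 5 among probes detected on all 10 arrays and 5 to 8 with 1 array left out, the lowest without untreated replicate 4. They numbered 0 with an estimated correlation, 0 with fry, 5 with fry in either direction and 0 with the exact permutation of list means, by which a single list cannot pass the adjustment. Camera with an estimated correlation differs from the main list test in that correlation, preset there to 0.01, and in the degrees of freedom of its test. Fry and the permutation also put another question to a list. None of these counts can therefore be put down to the correlation alone. For the other changes of list counts the cause was not tested. The log2 fold change of Stk11 ranged from 0.02 to 0.11 with 1 array left out and was -0.15 with array medians made equal, never past the threshold. Over all settings, 1358 of 1360 values of the other 57 named genes kept their direction, the exceptions being Mark3 with array medians made equal (-0.01) and Pck1 within array set A (0.00).

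Deviations of same-numbered mice correlated at 0.146, 0.239 and -0.166 for the numbers 1, 2 and 4. Mice numbered 1 and 2 were all in array set A, whereas untreated replicate 4 was in set B and LKB1 replicate 4 in set A. These values therefore cannot tell whether the replicate numbers pair the mice. With the replicate block, 0 genes and 10 lists were called, but respiratory chain (adjusted p = 0.100), drug metabolism (0.468) and SUMO genes (0.21) lost their call. The list of matrix genes, not called otherwise, reversed there to a median of -0.105 (adjusted p = 0.0238, camera). That fit compares only the mice numbered 1, 2 and 4. Matrix list means were -0.21, -0.37 and -0.10 in LKB1 replicates 1, 2 and 4. They were -0.06, 0.13 and 0.66 in LKB1 replicates 5, 6 and 7, which do not enter that comparison. The chip as a block was not run, as the files name no chip. Genes with signal near background, such as Npas2, Per3, Birc5 and Sesn2, may have compressed fold changes, which was not tested.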

Other observations

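The tests on the Stk11 probe were chosen after the result was seen. Other gene groups differed little between the livers. Cell junction and cytoskeleton genes were higher in 19 of 26 members (median 0.06, adjusted p = 0.0859, camera; 0.0418 without untreated replicate 2, 0.0245 without LKB1 replicate 5, 0.0421 with an offset of 50 and 0.0297 with the replicate block) and complement and coagulation factors in 21 of 32 (median 0.04, adjusted p = 0.156; 0.0447 without LKB1 replicate 7, 0.0255 with the replicate block and 0.0274 within array set A). With an estimated correlation over all arrays, these junction and complement lists had adjusted p-values of 0.786 and 0.848. Ribosomal protein genes were lower in 36 of 48 members (median -0.05, adjusted p = 0.098, or 0.00115 with array medians made equal and 0.786 with an estimated correlation). Methionine cycle genes were lower in 14 of 19 (median -0.06, from -0.102 to 0.005 with 1 array left out, adjusted p = 0.596, camera). The adjusted p was 0.779 for bile acid genes, 0.899 for cholesterol synthesis, 0.651 for urea and nitrogen, 0.899 for NRF2 targets, 0.779 for mTORC1 and autophagy, 0.679 for insulin signalling, 0.651 for matrix genes, 0.779 for fetal and tumour genes and 0.973 for growth hormone and sex-biased genes, with list medians between -0.01 and 0.04. Matrix genes were lower in array set A (unadjusted p = 0.0504) and higher in set B (unadjusted p = 0.00906).

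5 lists had an adjusted p under 0.05 for change in either direction (fry): p53 targets (0.00152), immediate early genes (0.0119), and clock, cell cycle and cytokine genes (0.0251 each). Of these, only the clock list was also called by camera at the preset correlation.

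Stk11 mRNA did not differ measurably in livers said to overexpress LKB1. The probe may not see the plasmid's transcript, and the lower 95% limit of the fold change, 0.922, leaves this open along with low delivery of the plasmid to the liver by the time of collection.

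One hypothesis for the higher Dusp1 and Cdkn1a, both targets of glucocorticoids, is a stress response in handled and injected mice. It was named with 9 other glucocorticoid targets before their values were seen. Their mean was higher by 0.167 in LKB1 livers with an exact permutation p of 0.176, and 5 were higher and 4 lower, so the test did not decide.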
